A study of Mus musculus with 80 samples.

How the data were processed

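Barcoded reporters were measured in 4 pools of EBRTcH3 cells, a mouse embryonic stem cell line that makes the tetracycline-controlled transactivator (tTA) from the ROSA26 locus. In a tet-Off system tTA binds its operator and activates the reporter, and doxycycline (dox) releases it. The titles, the plasmid and the design text name a tet-Off reporter, whereas the growth and treatment protocols also speak of an mPGK promoter; the titles were followed, and the conflict stays open. Reporters had been integrated in parallel with the piggyBac transposon, the assay known as TRIP, so that each cell pool held many integrations, each marked by its own barcode. Per the labels' protocols, transfected cells with low eGFP were sorted and grown for 5 days, small pools were expanded for 7 days, and each pool was divided into 2 cultures grown apart for 7 more days. Each culture was then spread over 4 dox doses (none, 0.01 ng/ml, 0.1 ng/ml and 100 ng/ml) and harvested for RNA and genomic DNA 72 h later. The 2 cultures are the replicates. Because both come from 1 pool, p-values from them measure the spread between such cultures and their libraries, which is technical per the labels.

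Of the 80 samples in the labels, 64 are RNA or DNA barcode libraries (4 pools, 4 doses, 2 replicates and 2 assays), and 16 are libraries that mapped the integrations. The deposited table holds read counts per barcode, not normalized, with a chromosome, position and strand for each reporter. Barcode reads from cDNA and from genomic DNA are separate count columns per the file headers. The 16 mapping libraries enter only through the positions. Bowtie2 2.0 and the mm9 build are named in the submitters' processing notes, without the role of either; how barcodes were called and filtered is not given in the sources used here. The lowest DNA count in the table is 5. The highest reporter position on chromosome 1, 197024744, lies beyond the last gene end of the GRCm38 gene table at hand, so that table was not used for positions, and gene features and gene lists were not analysed here. Coordinates are those of the deposited table, in mm9. The table had 0 columns of sample values that were left unused.

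Reporters with fewer than 10 DNA counts in any DNA library of their pool were left out (118 of 10903), which left 10785. RNA to DNA ratios were tested with edgeR 4.0.16 in R 4.3.3. Per pool, 1 quasi-likelihood model covered its 16 libraries with terms for assay, dose and their interaction, TMM scaling within each assay, and Benjamini-Hochberg adjustment within the pool at 0.05. Every RNA library was scaled to the others, so a fall shared by all reporters is not measured: "higher" and "lower" are relative to the reporters that set the scaling. The SE given with an edgeR change is its absolute log2 value divided by the square root of the F statistic of its test. It is not an SE from the fit, and is unreliable where there is almost no RNA. DNA abundance was tested in the same way on the DNA libraries alone. Spread, rank agreement, neighbour and chromosome values used log2 RNA/DNA after division by library totals with a pseudocount of 1, averaged over the 2 replicates and centred within each pool. The noise-corrected SD is the square root of the covariance of the replicates over reporters. Dose trends over the 4 pools were tested by an exact permutation test of the doses within pools. Neighbour and chromosome tests used 100000 shuffles of values among reporters within pools and were two-sided unless stated. Neighbouring reporters resemble each other, so shuffles that treat reporters as independent give chromosome and window p-values that are too small; means of 1 Mb blocks were therefore tested as well, those for windows and for the change of X with dose last, after the results were seen. A change with dose in neighbour similarity was tested by swapping the dose labels of whole chromosomes. The statistic was first the mean product of values scaled over all reporters. A test on the difference of r itself was added after seeing the data, and its values are given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and DESeq2 1.42.0 were also used.

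RNA libraries held 729552 to 1840870 counts and DNA libraries 928128 to 1571280. Reads are PCR products without molecular identifiers, so intervals and floors cover counting error only. At dox 100, a reporter with RNA in a single replicate had a median count of 46 to 94 there, depending on the library, and 2.78% to 7.20% of the non-zero counts were at most 10. Where RNA was 0 in both replicates, a fold is given as a bound against a floor of 3 counts over the group. Such a bound holds for read counts and not for RNA levels. The model was tested on simulated counts for dox 100 against 0 with 10785 reporters and 200 changed reporters per pool, 50 for each size. It recovered 47.5% of changes of −4 on the log2 scale, 8.00% of −2, 5.50% of 2 and 61.0% of 4, and called 0.0705% of unchanged reporters. The simulated changes were few and equal in number in both directions. In the data, 5435 reporters were called lower and 1174 higher at dox 100. The simulated rates, and the scaling under them, therefore need not hold for that contrast. Whether they hold with the zero counts and the wider replicate spread of dox 100 was not tested.

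The replicate numbers pair samples by the labels, since each of the 2 cultures of a pool was divided over the doses. The replicate differences of log2 counts had correlations between doses of −0.0537 to 0.0414 for RNA and −0.051 to 0.0463 for DNA. Fits with the replicate as a block were run as an alternative. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom was 4.51 for RNA and 27.9 for DNA. For RNA it was 4.51 to 5.98 at dox 0 and 59.2 to 91.5 at dox 100. Over reporters with RNA in either replicate, the Pearson r of log2 RNA counts was 0.974 to 0.985 at dox 0. At dox 100 it was 0.415 to 0.496. The model shared its estimate of spread over all doses, so standard errors and p-values at dox 100 do not reflect this difference. The tests and most alternatives were chosen before the data were examined. The alternatives were other scalings, filters, tools and models, left-out replicates and pools, other pseudocounts, and ranks in place of values. Reporters are named by a rule that was also fixed then. It takes the 5 largest increases and the 5 largest decreases at dox 100 among calls with the same direction in both replicates, and 3 of each at dox 0.1. It also takes the 5 highest and the 5 lowest reporters at dox 0 with at least 100 DNA counts in each dox 0 replicate, and the 3 closest pairs. Direction in each replicate was read from the log2 ratios with the pseudocount. Where a replicate had no RNA at either dose, as in 4 of the 5 increases at dox 100 and 2 of the 3 at dox 0.1, its direction came from the pseudocount, the library totals and the DNA, so the rule did not show agreement of the replicates for these. Of the 40 pairs that tie at 1 bp, the first 3 in genome order are given. The rule gave 32 entries for 30 reporters.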

Results

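The 4 pools held 2241 (A), 2263 (B), 3127 (C) and 3154 (D) reporters past the DNA minimum. Of these 10785 reporters, 10576 lie on autosomes, 203 on X and 6 on Y. Each pool had 2 RNA and 2 DNA libraries at each of 4 dox doses. RNA libraries at dox 0 held 1395690 to 1840870 counts with medians of 179 to 327 per reporter. At dox 100 they held 729552 to 1355706 counts with a median of 0. DNA medians ranged from 226 to 523 at dox 0 and from 227 to 500 at dox 100. The comparisons ask how the expression of a reporter depends on its place in the genome, and how that dependence moves with the dox dose.

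Without dox, nearly every reporter gave RNA, and their levels spread widely. Only 0.274% ± 0.134 (SD, n = 4 pools) had no RNA count in either replicate. The noise-corrected SD between reporters was 1.99 ± 0.035 on the log2 scale (SD, n = 4 pools), and the replicates had a Pearson r of 0.90 ± 0.0155. The top 1% of reporters took 11.9% ± 0.591 of the RNA counts and 5.38% ± 0.499 of the DNA counts (SD, n = 4).

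The highest reporter at dox 0 lay in pool C on chromosome 19 at 46574024 (plus strand), at 5.71 ± 0.369 above its pool mean on the log2 scale (SD, n = 2 replicates). It was followed by reporters on chromosome 4 at 137026173 (5.53, pool A), chromosome 2 at 168738379 (5.46, pool B), chromosome 4 at 128924279 (5.39, pool A) and chromosome 4 at 49071639 (5.16, pool C). At dox 100 the log2 change of the top reporter was 0.36 ± 0.36 (SE; edgeR adjusted p = 0.403), and that of the pool A reporter at 137026173 was −0.52 ± 1.24 (adjusted p = 0.739). The other 3 were lower: −4.73 ± 1.35 at 49071639 on chromosome 4 (SE, edgeR adjusted p = 0.00977; 120 and 1 RNA counts at dox 100), −3.09 ± 0.39 on chromosome 2 (adjusted p = 5.26e-05) and −1.40 ± 0.48 at 128924279 on chromosome 4 (adjusted p = 0.0248). The lowest reporters had many DNA counts and almost no RNA. The pool B reporter on chromosome 11 at 29350554 had 0 RNA counts in both dox 0 replicates beside 11969 and 14021 DNA counts. Those on chromosome 2 at 137118207 (pool B), chromosome 3 at 8053403 (pool B), chromosome 7 at 144770516 (pool A) and chromosome 17 at 10643091 (pool C) had at most 2 RNA counts in any dox 0 replicate, so their levels were limited by depth.

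Expression at dox 0 followed genomic position. Pairs of reporters less than 10 kb apart had a Pearson r of 0.354 over 1450 pairs, pairs 10 to 100 kb apart 0.311 over 7147 pairs, and pairs 100 kb to 1 Mb apart 0.188 over 51007 pairs. Each exceeded all shuffles of the permutation test (p = 1e-05, the smallest that 100000 shuffles can give; adjusted over 12 values, 1e-05). Pairs from different pools, which share no culture, had an r of 0.382 under 10 kb over 1079 pairs. By the deposited positions, 0 pairs of reporters shared a position and 0 lay 2 to 5 bp apart. In 40 pairs the positions were 1 bp apart, in each case on opposite strands. Of these, 39 passed the DNA minimum and had an r of 0.498 at dox 0 (permutation p = 0.00129). The first such pair on chromosome 1, at 9879009 (pool A) and 9879010 (pool C), stood at 1.20 and −0.47 on the log2 scale. The pair at 68331356 (pool C) and 68331357 (pool A) stood at −4.08 and −4.60, and the pair at 189244681 and 189244682 (both pool C) at −0.51 and −1.25.

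**Figure D1:**
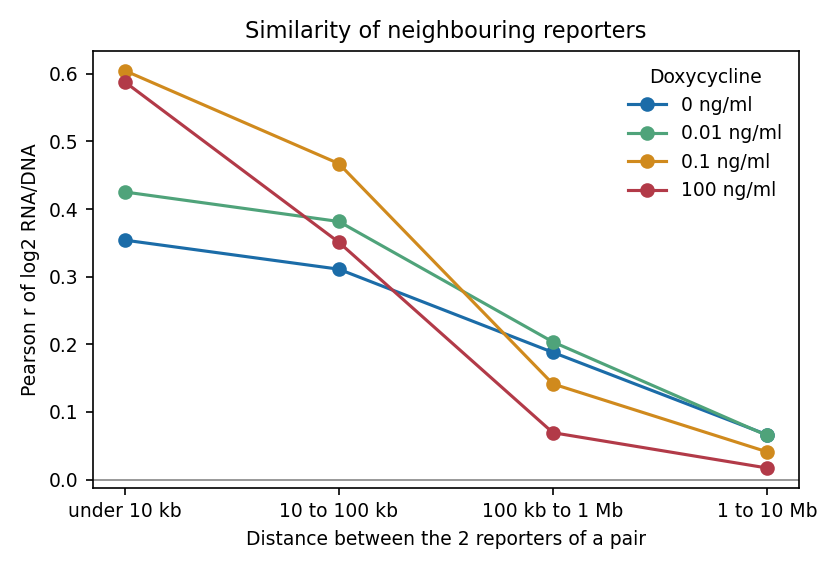
Pearson r of log2 RNA/DNA (y axis) between pairs of reporters on the same chromosome, by their distance (x axis, 4 classes), with a line for each dox dose. Under 10 kb r rises from 0.354 at dox 0 to 0.588 at dox 100, and at 100 kb to 1 Mb it falls from 0.188 to 0.0694.

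Whole regions stood apart at dox 0. Of 440 windows of 5 Mb with at least 10 reporters, 53 were higher and 57 lower than the rest of the genome (permutation test, Benjamini-Hochberg adjusted over the windows). The lowest was on chromosome 4 from 75000001 to 80000000, where 11 reporters from 4 pools averaged 3.77 below the others (a difference of −3.77 ± 0.71 on the log2 scale, SE over reporters, permutation p = 1e-05, adjusted 0.000367). On chromosome 1 the windows from 100000001 to 105000000 and from 110000001 to 115000000 lay at −3.69 ± 0.50 and −3.61 ± 0.41 (SE, 10 reporters each). The highest was on chromosome 7 from 1 to 5000000, where 20 reporters lay at 2.02 ± 0.37 (SE; permutation p = 4e-05, adjusted 0.000978). The window from 25000001 to 30000000 on that chromosome stood at 1.99 ± 0.32 with 32 reporters, and chromosome 15 from 75000001 to 80000000 at 1.94 ± 0.22 with 49 reporters. At dox 100, 24 windows were higher and 1 lower. These counts treat reporters as independent. With means of 1 Mb blocks as the units, 1 window was higher and 3 lower at dox 0: those named on chromosomes 4 and 1, and the one from 25000001 on chromosome 7 (adjusted p = 0.0308, 0.0473, 0.0352 and 0.0352). The other 2 named windows did not pass (0.25 and 0.0757). At dox 100, 1 was higher and 0 lower.

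Chromosomes differed as well. At dox 0, chromosomes 2, 7, 9, 11 and 19 lay above the others and chromosomes 1, 3, 13, 14, 18 and X below (permutation test, adjusted over 20 chromosomes). Chromosome 11 was 0.56 ± 0.08 higher (SE, 649 reporters, adjusted p = 0.0001) and chromosome 3 stood at −0.53 ± 0.09 (SE, 628 reporters, adjusted p = 0.0001). X reporters stood at −0.59 ± 0.16 against the rest (SE, 203 reporters, permutation p = 4e-05, adjusted 0.00016), and lay below the autosomes in each of the 4 pools (−0.55, −0.68, −0.84 and −0.33 in A to D). With means of 1 Mb blocks as the units, chromosomes 7, 9, 11 and 19 were higher and 1, 3 and X lower (X −0.75, adjusted p = 0.000267), and 2, 13, 14 and 18 no longer passed. With a DNA minimum of 100, X no longer passed the threshold (−0.41, adjusted p = 0.0504). At dox 100, chromosomes 11 and 17 were higher and 13 lower over reporters, but with 1 Mb blocks 17 and 13 did not pass (adjusted p = 0.39 and 0.248), 11 did (0.0142) and so did 7 (higher, 0.0461). There X stood at 0.12 ± 0.26 (SE, adjusted p = 0.744), with values of −0.06, 0.52, −0.47 and 0.45 in pools A to D. In units of the SD at each dose, X changed from −0.288 to 0.0317, a difference of 0.319 (permutation p = 2e-05). With means of 1 Mb blocks the difference was 0.425 (permutation p = 1e-05). At dox 100, 58.5% of reporters had no RNA count, and with the pseudocount DNA counts set their values. The chromosome values at that dose, and the change of X, therefore mix lost detection with level.

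**Figure D2:**
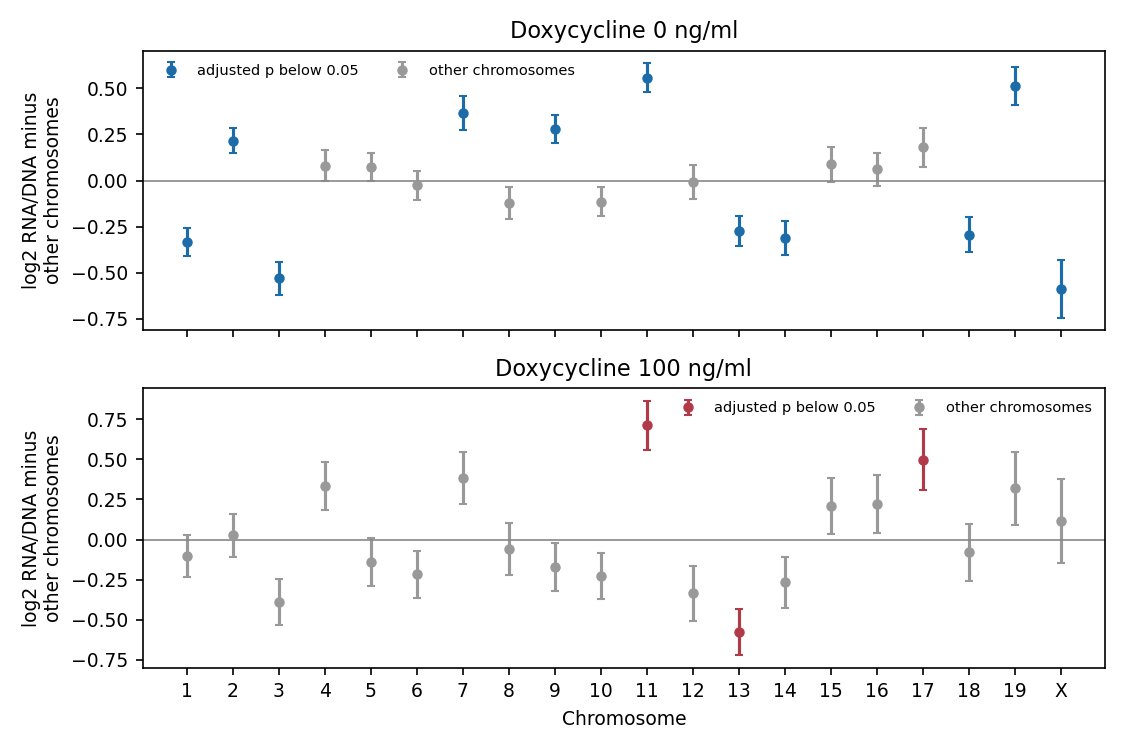
Mean log2 RNA/DNA of the reporters on each chromosome minus that of all others (y axis) for the 19 autosomes and X (x axis), at dox 0 (top) and dox 100 (bottom), with bars of 1 standard error over reporters. Coloured points passed an adjusted p of 0.05; X lies at −0.59 at dox 0 and at 0.12 at dox 100.

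With 100 ng/ml dox, 50.4% of the reporters had a lower RNA to DNA ratio than at dox 0 and 10.9% a higher one, relative to the scaling. These were 5435 and 1174 of 10785, 6609 in all (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted within pools). The median log2 change was −4.12. Over the alternatives it ran from −2.91 (DNA minimum of 100) to −7.36 (without dox 100 replicate 1), and it was −6.36 without replicate 2. In pools A to D, 51.0%, 48.5%, 51.3% and 50.4% of the reporters were lower, and 10.75%, 12.06%, 10.04% and 10.97% higher. Of the lower reporters, 86.9% had no RNA count in either dox 100 library, while 99.0% of the higher ones had RNA in both. Both replicates moved in the direction of the call for 84.8% of the higher and 100% of the lower reporters, by ratios over library totals. Scaling by library totals gave a median change of −5.15, so it favoured falls and opposed rises. These shares are therefore no measure of replicate agreement, and the share over all reporters was not computed. The share of higher calls depended on the scaling: it was 17.8% of the calls with TMM, 11.2% (775 of 6911) with DESeq2 size factors and 8.72% (620 of 7112) with library totals, under which the median change moved to −4.83 and −5.15. At dox 0.01 the pool medians of the higher reporters averaged 1.59 ± 0.09 above the pool mean. Those of the lower reporters averaged −0.35 ± 0.03, and those of the 4176 reporters with neither call 0.44 ± 0.10 (SD, n = 4 pools). The dox 0.01 libraries are not part of the contrast, but they enter the shared spread and the scaling of its model.

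The 5 largest decreases at dox 100 were strong reporters with no RNA count left in either dox 100 library. The pool A reporter on chromosome 2 at 168351336 had 7111 and 7952 RNA counts at dox 0 and 0 in both dox 100 replicates, at least 1669-fold lower (edgeR adjusted p = 4.5e-07). Those on chromosome 4 at 125088305, chromosome 7 at 116769840 and chromosome 11 at 116892520, all in pool A, were at least 1305-fold, 1301-fold and 1299-fold lower. The pool B reporter on chromosome 1 at 136892811 was at least 903-fold lower (edgeR adjusted p = 7.49e-07). Of the 5 largest increases, 1 had RNA in both dox 100 libraries: the pool D reporter on chromosome 7 at 30200390, with 8 and 0 RNA counts at dox 0 and 142 and 450 at dox 100, a fitted log2 change of 8.39 ± 1.27 (SE, edgeR adjusted p = 0.000182). The others, in pool B on chromosome 11 at 29350554, chromosome 8 at 119226650, chromosome 14 at 75682903 and chromosome 12 at 105991907, had no RNA at dox 0 and 45 to 99 counts in a single dox 100 library. They belong to the 12 higher calls of that kind. When that library was left out, no RNA count remained at dox 0 or dox 100, so the sign of the fit carries no information. The fitted change then turned negative for those on chromosomes 11, 14 and 12. The one on chromosome 8 then lost its call. Paired by a replicate block, those on chromosomes 11 and 12 lost theirs (adjusted p = 0.05001 and 0.0708), and with DNA as an offset or without either dox 0 replicate all 4 did.

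Reporters with the same call lay near each other. Next to a higher reporter of another pool less than 10 kb away, 60.5% of reporters were also higher, against 12.2% next to one that was not (shares over pairs, one-sided permutation p = 1e-05, the smallest 100000 shuffles can give, adjusted 2e-05). At 10 to 100 kb the shares were 31.5% and 12.5%, and at 100 kb to 1 Mb 12.8% and 11.1% (adjusted p = 2e-05 and 0.000768). For lower reporters the shares were 54.8% and 22.3% under 10 kb, 50.8% and 35.9% at 10 to 100 kb, and 50.6% and 49.0% at 100 kb to 1 Mb (adjusted p = 2e-05, 2e-05 and 0.00143). These p-values come from a second test, added after the first was seen, which shuffles calls within pools among the reporters with such a neighbour; of those with one under 10 kb, 35.3% were lower against 50.4% of all. The first test shuffled among all reporters and gave adjusted p = 3e-05, 3e-05 and 0.00018 for higher calls, and 0.0166, 0.325 and 0.324 for lower ones, so the likeness of lower calls beyond 10 kb depends on the choice of test. Reporters linked by gaps of at most 50 kb formed 76 chains of 6 or more. Of these, 21 had at least 50 percent higher reporters, 28 had no higher one and 2 had lower ones only. How many chains of each kind calls placed at random would give was not computed. These counts by themselves therefore do not show clustering. The following chains were chosen after their values were seen. On chromosome 5, from 104127348 to 104153604, all 6 reporters (2 pools) were higher. On chromosome 2, from 20573004 to 20660550, 7 of 8 reporters (3 pools) were higher, and on chromosome 11, from 107171483 to 107296994, 7 of 11 (4 pools). The 2 chains of lower reporters only, with 6 each, began at 103134791 on chromosome 2 and at 47845968 on chromosome 19.

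The intermediate dose of 0.1 ng/ml changed fewer reporters. Relative to the scaling, 2138 reporters were lower and 978 higher than at dox 0, 3116 in all. The median log2 change was −0.80, and it was −1.76 with DESeq2 size factors and −1.96 with library totals. Higher calls were 31.4% of the total with TMM, 14.1% (541 of 3841) with DESeq2 size factors and 11.5% (472 of 4100) with library totals. RNA counts with the DNA as an offset gave 1768 calls, and leaving out dox 0 replicate 1 or 2 in every pool gave 1841 and 1810. The largest decreases lay in pool A, on chromosome 5 at 89620728, chromosome 3 at 117042623 and chromosome 9 at 110268192. These reporters had 0 RNA counts in both dox 0.1 replicates. In read counts they were at least 261-fold, 232-fold and 212-fold lower against the floor of 3 (edgeR adjusted p = 0.00816, 1.77e-05 and 0.00131). The first had 155 RNA counts in 1 of the dox 100 libraries, and lost its call with DNA as an offset (adjusted p = 0.062), without either dox 0 replicate (0.0657 and 0.0748) and without dox 0.1 replicate 2 (0.0529). The largest increases had no RNA at dox 0 and few counts at dox 0.1: 3 and 15 on chromosome 13 at 63985379 (pool B), 29 and 0 on chromosome 4 at 110876144 (pool C), and 0 and 18 on chromosome 3 at 8053403 (pool B), where the fitted change turned negative without dox 0.1 replicate 2. That on chromosome 4 moved from 8.16 to 0.79 without dox 0.1 replicate 1. In both cases no RNA count was then left at dox 0 or dox 0.1, so the sign of the fit carries no information. The change on chromosome 13 moved from 8.59 to 7.45 without dox 0.1 replicate 2. All 3 lost their calls with DNA as an offset and without either dox 0 replicate, and with a replicate block the first and the last did (adjusted p = 0.0512 and 0.0523).

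At 0.01 ng/ml, 2 reporters passed the edgeR test, both higher. With an unadjusted p below 0.05 there were 532, and the DESeq2 Wald test called 91. Both were chosen after their values were seen. The pool A reporter on chromosome 17 at 81202701 (minus strand) was 2.13 ± 0.28 higher on the log2 scale, relative to the scaling (SE, edgeR adjusted p = 0.0238). Its RNA counts were 1723 and 2273 at dox 0 and 3848 and 3829 at 0.01 ng/ml, beside DNA counts of 987 and 898 and of 593 and 414. The pool C reporter on chromosome 1 at 168056327 (plus strand) was 3.91 ± 0.53 higher, also relative to the scaling (SE, edgeR adjusted p = 0.0327). Its RNA counts were 466 and 509 at dox 0 and 1235 and 1002 at 0.01 ng/ml, and its DNA counts fell from 190 and 152 to 36 and 25. At dox 100 the RNA counts were 28488 and 31434 for the first and 6089 and 5304 for the other. Paired by a replicate block, the reporter on chromosome 1 lost its call (adjusted p = 0.0799) and that on chromosome 17 kept it (0.0456). With DNA as an offset neither passed. Without any single replicate of either dose, 0 reporters passed.

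Differences between reporters widened with dose. The noise-corrected SD was 2.31 ± 0.029 at 0.01, 3.24 ± 0.139 at 0.1 and 3.42 ± 0.094 at 100 ng/ml (SD, n = 4 pools), 1.43 ± 0.07 above dox 0 at the top dose. It rose in every pool (exact permutation test of doses within pools, two-sided p = 6.03e-06, the smallest that the 331776 arrangements allow). The share of reporters without an RNA count rose from 0.516% to 1.49%, 27.5% and 58.5%, and the share of RNA counts in the top 1% of reporters from 11.9% to 14.6%, 33.4% and 46.2% (both with the same exact p). The size of the widening depended on the value given to zero counts: it was 2.48 with a pseudocount of 0.1, 0.80 with 5 and 0.24 with 50, the last added after seeing the data. The share of DNA counts in the top 1% of reporters stayed between 5.27% and 5.44% on average (exact p = 0.354).

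**Figure D3:**
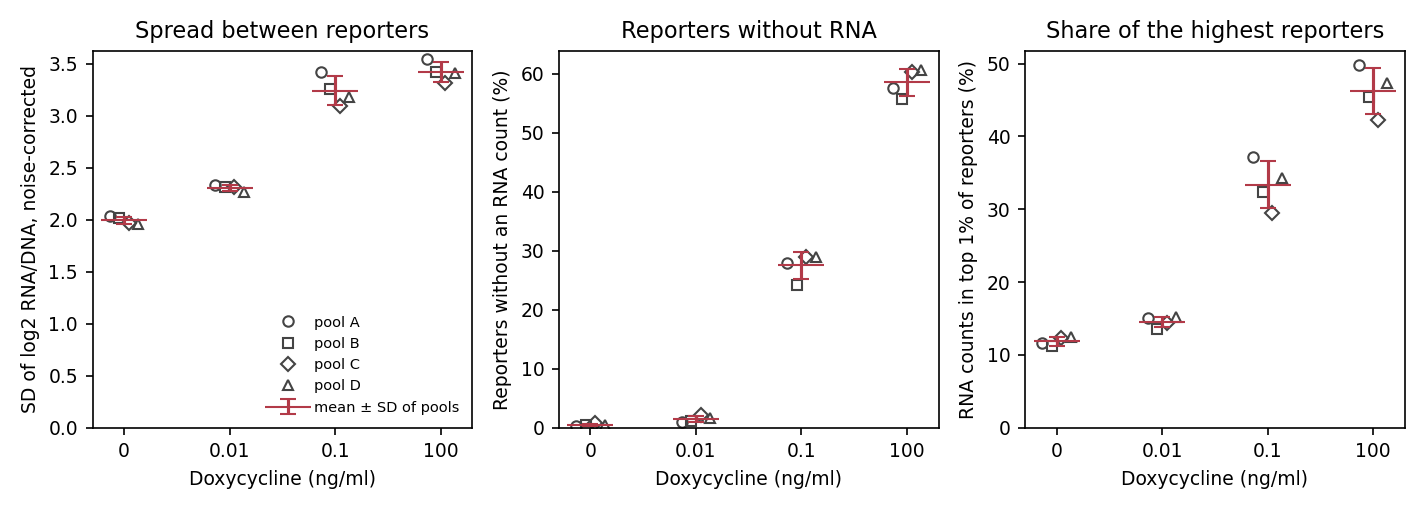
Noise-corrected SD of log2 RNA/DNA between reporters (left), reporters without an RNA count in percent (middle) and RNA counts in the top 1% of reporters in percent (right) at 4 dox doses on an evenly spaced axis. Open symbols are the 4 pools, and bars the mean ± SD of the pools; the means rise from 1.99 to 3.42, from 0.516% to 58.5% and from 11.9% to 46.2%.

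By log2 RNA/DNA, the order of reporters was kept at the lowest dose and less so at the higher ones, where many had no RNA count. Spearman's rho of reporters with dox 0 was 0.933 ± 0.00634 at 0.01, 0.747 ± 0.0258 at 0.1 and 0.437 ± 0.0265 at 100 ng/ml (SD, n = 4 pools), a correlation across reporters, which are not independent replicates. The rho between replicates within a dose was 0.902 at dox 0 and 0.919, 0.820 and 0.679 at the other doses. Corrected for replicate noise, the Pearson correlations with dox 0 were 0.978, 0.791 and 0.504. At 0.1 and 100 ng/ml, 18.3% and 48.1% of reporters had no RNA count in either replicate. With the pseudocount, DNA counts set the order of these reporters. DNA counts repeat between replicates, so the correction does not remove this. Both measures therefore mix lost detection with a changed order of sites.

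Similarity of neighbours was higher under 10 kb at every dox dose than at dox 0, and at 100 kb to 1 Mb lower at the upper doses. Under 10 kb, r was 0.425 at 0.01 ng/ml, 0.605 at 0.1 and 0.588 at 100, against 0.354 at dox 0, and was higher on 19, 20 and 19 of 20 chromosomes (permutation of dose labels over chromosomes, adjusted p over 9 tests = 3.6e-05, 3e-05 and 3e-05). With ranks within pools the value at dox 100 was 0.491 against 0.382 at dox 0, a smaller rise of 0.109 (adjusted p = 0.00147). At 10 to 100 kb it was 0.382, 0.467 and 0.351 at these doses, against 0.311 at dox 0 (adjusted p = 6e-05, 3e-05 and 0.0314). The last of these depended on the choices made: the statistic used first gave 0.000116, and r itself passed in 5 of 13 alternatives, 1 of which leaves its pairs unchanged, and turned sign in 2. At 100 kb to 1 Mb, r was slightly higher at 0.01 ng/ml (0.204 against 0.188, 16 of 20 chromosomes, adjusted p = 0.00192), but not detectably with a pseudocount of 50 (adjusted p = 0.445). It was lower at 0.1 (0.141, 18 of 20, adjusted p = 0.000193) and at dox 100 (0.0694, 19 of 20, adjusted p = 3.6e-05). The pairs 1 bp apart had an r of 0.625 at dox 100 (permutation p = 3e-05).

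DNA abundance, the background measured in the same cells, did not change detectably between dox 0 and dox 100, the only doses tested for it. No reporter passed the edgeR test of DNA counts at dox 100 against 0 (0 of 10785), 486 (4.51%) had an unadjusted p below 0.05, and the DESeq2 Wald test called 1. The median log2 change was −0.00217.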

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

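All tests in this part were chosen after the results were seen, apart from the search for samples far from the others.

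Among 48 sets of 4 pool values, 1 held a pool far from the rest, where chance gives about 1 in 20. In pool C, 0.799% of reporters had no RNA count at dox 0, against 0.379% to 0.444% in the other pools.

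Neighbour similarity differed between doses. Relative to dox 0, r of pairs under 10 kb was 0.0712 higher at 0.01, 0.251 higher at 0.1 and 0.234 higher at 100 ng/ml. At 10 to 100 kb the differences were 0.0705, 0.156 and 0.0398, the last of which turned sign in 2 of 13 alternatives. At 100 kb to 1 Mb they were 0.0155, −0.0467 and −0.119. X reporters differed between doses too: relative to the autosomes they stood 0.319 SD higher at dox 100 than at dox 0. Lost detection at dox 100 can move this value as well, and was not separated from it.

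The first pattern is the changed order of log2 RNA/DNA at dox 100, where many reporters had no RNA count. Loss of cDNA molecules would be independent in the 2 cultures of a pool. It was taken to leave the dox 100 replicates no more alike than dox 100 is to the less noisy dox 0. The rho between dox 100 replicates was instead 0.286 ± 0.0267 higher (SD, n = 4 pools). It was 0.289 higher among reporters with at least 100 DNA counts. This cannot decide the question, because 48.1% of reporters had no RNA count in either dox 100 replicate. With the pseudocount their values follow DNA counts, which repeat between the replicates (Pearson r of log2 counts 0.730 to 0.814). Genomic DNA carried into the cDNA would make RNA counts follow DNA counts, but their mean rho was 0.183 over 8 libraries (0.152 to 0.22). Independent loss of molecules still adds noise to each value at this dose. The dose itself stays open as the biological explanation, untested.

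The second pattern is the likeness of reporters within 10 kb at dox 100. A barcode effect would make 2 reporters with the same barcode alike, but 370 such pairs from different pools had an r of −0.0513 (permutation p = 0.318). A shared pool, clone or library would not link pairs from different pools, whose r was 0.590. Transcription that enters the reporter from one side only would spare pairs on opposite strands, whose r was 0.559 against 0.613 on the same strand. The permutation test of this difference used a form of r without the mean of the pairs subtracted (p = 0.194). These values argue against each as the whole cause. No biological explanation was tested.

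The third pattern is the shorter reach of that likeness. Noisier values would lower r by the same factor at all distances only if the reporters at each distance were equally noisy. The ratio of r at 100 kb to 1 Mb to r under 10 kb moved from 0.531 to 0.118. That was a change of −0.413 ± 0.0441 (jackknife SE over 20 chromosomes). The reporters differed, however. Of those with a neighbour of another pool under 10 kb, 35.3% were lower at dox 100, against 50.4% at 100 kb to 1 Mb. The ratio therefore cannot decide whether noise shortened the reach. With a pseudocount of 50 the change was −0.406 ± 0.0388, so the fall did not hinge on the value given to zero counts. No pseudocount restores the order of the 58.5% of reporters without an RNA count at dox 100. Lost detection as a cause therefore cannot be judged in this way. The dose stays open as the biological explanation, untested.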

How the results depend on the processing

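The spread, the neighbour r at dox 0 and the chromosome result (followed by X) kept their direction under all alternatives run for them. The change of r with dose was run under 13 alternatives, chosen after seeing the data. Under 10 kb all kept direction and call (0.109 to 0.285 at dox 100), and so did 100 kb to 1 Mb at the upper doses (−0.132 to −0.113 at dox 100). At 10 to 100 kb the change at dox 100 ranged from −0.0274 (ranks) to 0.0496, past the threshold in 5. X lost its call with a DNA minimum of 100 (−0.409, adjusted p = 0.0504), a filter that also leaves fewer reporters. With 1 Mb blocks, chromosomes 2, 13, 14 and 18 lost their calls at dox 0 (adjusted p = 0.0948, 0.724, 0.0567 and 0.724), and at dox 100 chromosomes 13 and 17 lost theirs and 7 gained one. Added after seeing the data were the pseudocount of 50, the removal of pairs 1 bp apart (r under 10 kb 0.350), 1 Mb blocks (X −0.754), and left-out replicates for X (−0.633 to −0.543). The widening from dox 0 to 100 ranged from 0.238 to 2.48 over pseudocounts, and was 1.26 with the scaled median absolute deviation and 1.40 to 1.45 without 1 pool. With a single replicate, rho of dox 100 with dox 0 was 0.377 to 0.403, and 0.428 to 0.448 without 1 pool; the cause was not tested. Calls at dox 100 ranged from 4622 (DNA minimum of 100, with 7415 reporters tested) to 7556 (without dox 100 replicate 1). At dox 0.1 there were 1768 with DNA as an offset, and 1810 to 3586 without 1 replicate, where fewer samples enter. At dox 0.01 there was 1 call with DESeq2 size factors and 1 with library totals, 4 with a DNA minimum of 100, 91 with the DESeq2 Wald test (3256 adjusted p not given), 0 with DNA as an offset, and 0 without any 1 replicate. For DNA abundance, the DESeq2 Wald test called 1 and left-out replicates gave 1 to 4. Apart from construction, the cause of these moves was not tested.

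Paired fits with a replicate block gave 6347 calls at 100 ng/ml, 2718 at 0.1 and 2 at 0.01, and 0 for DNA abundance. The block moved no count of calls by over 1.5 times, but of the 2 calls at 0.01 only 1 was shared with the unpaired fit. Among the 16 named changes it ended 4 calls, given in the report. Where a replicate is left out, the lone library is assumed to vary like the others in the model.

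For the named changes, 136 alternative values kept direction and call, 33 lost the call and 4 turned sign, each where the only library with RNA was left out: chromosome 11 at 29350554 (−0.163 without dox 100 replicate 1, up to 10.7 without another), chromosome 14 at 75682903 (−0.034 without dox 100 replicate 1, up to 10.4), chromosome 12 at 105991907 (−0.172 without dox 100 replicate 2, up to 9.40) and chromosome 3 at 8053403 (−0.107 without dox 0.1 replicate 2, up to 8.40). Without that library neither dose of the comparison had an RNA count, so these 4 signs carry no information. Not run were mapped reporters only, since every reporter has a position, and the spread without a replicate, which needs both. Annotated features, which need an mm9 annotation, were not run either. Depth limits the lowest reporters: a count of 0 at dox 100 bounds a level but does not show silence.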

Other observations

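The tests in this part were chosen after the results were seen.

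Of 6 reporters on Y, 5 lay among the lowest at dox 0, between percentiles 0.612 and 6.46 of all reporters, and had no RNA at dox 100. The pool D reporter at 2857937 stood at percentile 94.6, with 1516 and 1701 RNA counts at dox 0 and 61 and 1 at dox 100.

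The top 5% of reporters in a dox 100 replicate were found in the top 20% of the other dox 100 replicate in 98.5% ± 0.535 of cases, and in the top 20% of the other dox 0 replicate in 64.4% ± 4.99 (SD, n = 4 pools). For the top 5% at dox 0 the share within dox 0 was 91.1% ± 4.57.

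Barcode GC content had a Spearman rho with log2 RNA/DNA between −0.0129 and −0.0067 over the doses. At dox 0, 370 pairs of reporters with the same barcode in different pools had an r of 0.042 (permutation p = 0.419). The orientation of neighbours made no detectable difference at dox 0 either: under 10 kb r was 0.377 on the same strand and 0.316 on opposite strands. The permutation test of this difference used a form of r without the mean of the pairs subtracted (p = 0.578, adjusted over 4 tests 0.771). Pairs 1 to 10 Mb apart had an r of 0.0664 at dox 0 and 0.0172 at dox 100.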
